A study of Arabidopsis thaliana with 18 samples.

How the data were processed

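RNA was sequenced from whole Arabidopsis thaliana seedlings of the Col-0 ecotype and of 5 mutant lines, with 3 libraries per genotype and 18 libraries in all. Per the labels, seedlings stood on MS medium for 14 days at 22 °C with 16 h of light and 8 h of dark, RNA came from a plant column kit, and libraries were made with a stranded mRNA kit that captures RNA with poly(A) tails. Per the submitters' processing notes, the tools used were cutadapt, HISAT2, SAMtools and featureCounts, with the genome build TAIR10. Their versions, their settings and whether counting used the strand are not given in the sources used here. The deposited values are whole-number counts of reads per gene, made by the authors with no normalization, in 1 table with a column for each library. Column names gave the genotype and replicate number of each library, and 0 columns were left unused.

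The table holds 33602 genes, of which 8244 had no count in any library. Total counts ran from 7163359 to 10744318 per library. Symbols came from the RefSeq gene table (TAIR10.1), which matched 32835 of the identifiers, and from the gene lists. Coordinates are those of TAIR10.1, which carries the same chromosome sequences as TAIR10 under another annotation release.

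Each genotype was compared by edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM scaling and edgeR's default filter on low counts (filterByExpr). All 18 libraries entered 1 fit with genotype as the single factor and 12 residual degrees of freedom, so that all groups shared 1 estimate of the spread. The filter kept 18906 genes, which hold 99.905% of all counts, and 99.28% of them were matched to the RefSeq table. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, and the count with at least a 2-fold change is given beside it. The 7 comparisons between 2 genotypes set each mutant line against Col-0 and each double line against its hta9hta11 or arp6 parent. The 2 interactions ask whether the change between lines with and without the atchz1ab mutations differed between backgrounds. Levels are CPM, counts scaled to library sizes after TMM, as mean ± SD with n = 3, except for the genes on or off in arp6, whose CPM and thresholds use library totals without TMM. Log2 fold changes carry their standard errors, taken from the test statistic, and rest on a prior count that moderates genes with few counts.

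Genes with 0 counts in a whole group are given as a bound against a floor of 3 counts over the group. Genes with 1 to 3 counts in a group are given as the ratio of the counts, scaled by library sizes after TMM, with its 95% counting interval. Intervals and floors cover counting error only, because reads without molecular identifiers are not independent molecules. The common biological coefficient of variation was 3.08%. In a chi-square comparison of each of the 18 replicate pairs over genes, replicates differed by more than sampling noise, with chi-square per degree of freedom from 1.43 to 1.69, so that no library was counted as a copy of another. The labels do not say that replicates were grown or extracted separately, so p-values measure only the spread between these samples, which may be technical.

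In total, 19 lists of known genes were fixed before the data were examined, as were the test, the comparisons, the rule for named genes and all alternatives not described as added later. The lists are H2A.Z and SWR1 or INO80 machinery, FLC and its MAF relatives, flowering time regulators, floral organ identity, salicylic acid and immunity, jasmonate and wounding, heat shock, phosphate starvation, flavonoid and anthocyanin, glucosinolate, photosynthesis, circadian clock, auxin response, abscisic acid with drought and cold, DNA damage response, cell cycle and DNA replication, root markers, seed maturation and senescence. The last 3 lists and the floral list stand for organs or stages that a seedling sample could hold. The lists hold 395 genes, of which 334 were tested, and 1 gene, GI (AT1G22770), stands in both the flowering and the clock list. Each list was tested with camera (limma 3.58.1) at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 19 lists of a comparison. Camera compares the members with all other genes. It was repeated with a correlation estimated from the residuals, and fry was run as another test. The fry p-value tests whether a list's genes move, on balance, one way, and its mixed p-value whether they change in either direction, and neither compares the list with other genes. Member counts are given over all genes tested and adjusted over the list alone. Median, mean and test differed in sign for 21 of the 171 list tests, and 1 of these was called, photosynthesis in hta9hta11 against Col-0.

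The rule for named genes took, in each comparison of 2 genotypes, the mutated genes HTA9 (AT1G52740), HTA11 (AT3G54560) and ARP6 (AT3G33520) with HTA8 (AT2G38810), then FLC (AT5G10140) and its MAF relatives, then the 5 largest rises and 5 largest falls, and up to 4 members of each list with the smallest adjusted p. The largest changes had to reach a mean of 1 CPM over all libraries and show no overlap between the groups in CPM, which chance gives for 10% of unchanged genes with 3 libraries against 3. For an interaction the rule took the 5 smallest adjusted p in each direction. Genes named outside this rule are said to have been chosen after their values were seen. The labels and the RefSeq table do not tie the AtChz1 genes to identifiers, so their own transcripts are not analysed here.

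The transcripts of 348 named genes were searched against the exons of all annotated genes with BLAST+ 2.17.0, and 18 had a copy elsewhere of at least 95% identity over 50% or more of their exons. Exons of 12 of the 348 genes overlap another gene on the same strand, and 78 overlap a gene on the opposite strand. As the strand setting of the counting is not given, reads of the latter cannot be told apart from those of the opposite gene, and values of such genes are uncertain where this is said. Uncertain for near-identical copies are LHCB1.1 (AT1G29920), LHCB1.3 (AT1G29930) and the 18S and 5.8S ribosomal RNA genes, for an overlap on the same strand CA1 (AT3G01500), GLT1 (AT5G53460) and NRP1 (AT1G74560), and for one on the opposite strand FLC, COR15B (AT2G42530), AT2G05914, AT5G28919, AT5G66052 and, over smaller parts, PIE1 (AT3G12810), LNK2 (AT3G54500) and HSP101 (AT1G74310).

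Shared controls were handled by simulating 20 sets of unchanged groups against the 3 Col-0 libraries. The tests were run on simulated data drawn from the real means and library sizes, with 200 genes changed by known folds among the 18906. For atchz1ab against Col-0, edgeR recovered 17 of 50 genes changed 1.25-fold, 39 of 50 at 1.5-fold, 41 of 50 at 2-fold and 49 of 50 at 4-fold, with 12 false calls. DESeq2 recovered 133 of the 200 with 2 false calls, limma-voom 144 with 12. The interaction of atchz1ab with hta9hta11 recovered 130 of 200 with 11 false calls. The alternatives were size factors of the RLE kind, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, organelle genes left out, a fit of only the libraries compared, a 2-fold threshold and each replicate left out in turn. A likelihood ratio test with 1 assumed coefficient of variation of 0.1 for all genes was added after seeing how little the replicates differed. A count without genes near those silent or newly transcribed in arp6, and the organelle share with each replicate left out, were also added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.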

Results

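The transcriptomes of 14-day-old seedlings were compared between Col-0, the wild type, and lines mutated in parts of the pathway that places the histone variant H2A.Z in chromatin. H2A.Z replaces H2A in nucleosomes near gene starts. HTA9 and HTA11 encode H2A.Z proteins, and the hta9hta11 line carries the alleles hta9-1 and hta11-2. ARP6 is a subunit of the SWR1 complex, which exchanges H2A for H2A.Z, and the arp6 line carries arp6-1. AtChz1 proteins are named after the yeast chaperone Chz1 of H2A.Z, and the atchz1ab line is mutated in both AtChz1 genes. The remaining lines, atchz1ab hta9hta11 and atchz1ab arp6, combine these mutations. Each of the 6 genotypes had 3 libraries of 7163359 to 10744318 counts. In a principal component analysis of all tested genes the first component held 60% of the variance and set the 6 libraries carrying arp6 (54.6 to 69.7) apart from the other 12 (-37.0 to -26.7), and the second held 7.38%. All adjusted p-values of genes below are Benjamini-Hochberg values of edgeR's quasi-likelihood test over 18906 genes, all log2 fold changes are given ± SE, and all levels are CPM, counts scaled to library size, as mean ± SD with n = 3. Counts of list members adjusted over the list alone give the higher ones first. For every named gene said to have risen or fallen, all 3 libraries of the first genotype lay on the same side of all 3 of the second.

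The mutated genes were read first in every genotype. HTA9 (AT1G52740, chromosome 1, 19645236 to 19646485) stood at 93.3 ± 5.85 CPM in Col-0, 94.7 ± 3.91 in atchz1ab, 99.6 ± 3.63 in arp6 and 97.6 ± 4.14 in atchz1ab arp6. It stood at 42.7 ± 1.68 in hta9hta11 and 39.2 ± 2.73 in atchz1ab hta9hta11. It fell by 1.13 on the log2 scale in hta9hta11 (SE 0.06, edgeR adjusted p = 2.45e-36) and changed by -1.25 ± 0.06 in the line with atchz1ab (edgeR adjusted p = 1.19e-40). HTA11 (AT3G54560, chromosome 3, 20196140 to 20197726) stood at 19.5 ± 1.64 CPM in Col-0, 18.4 ± 0.891 in atchz1ab, 19.5 ± 0.878 in arp6 and 18 ± 1.07 in atchz1ab arp6. It stood at 0.832 ± 0.513 and 0.811 ± 0.236 in the lines carrying hta11-2 (edgeR adjusted p = 5.54e-40 and 1.68e-41, log2 fold changes -4.49 ± 0.21 and -4.59 ± 0.21). ARP6 (AT3G33520, chromosome 3, 14093656 to 14095588) had 714 counts over the Col-0 libraries, or 27.8 ± 2.27 CPM, and 0 counts in arp6, at least 229-fold lower. A single count in atchz1ab arp6 gave a ratio of 629.7 (113 to 24907), while the gene stood at 25.9 ± 1.13 CPM in atchz1ab, 27.5 ± 2.66 in hta9hta11 and 26.4 ± 2.3 in atchz1ab hta9hta11. The transcripts of both AtChz1 genes are not analysed here. HTA8 (AT2G38810), another H2A.Z gene (chromosome 2, 16219220 to 16220928), stood at 6.08 ± 1.37 CPM in Col-0 and was not called in any comparison with Col-0. In atchz1ab arp6 against arp6 it rose by 0.70 ± 0.20 (7.48 ± 1.7 against 4.62 ± 0.445 CPM, edgeR adjusted p = 0.00852), a call lost without arp6 replicate 1 (0.61) or atchz1ab arp6 replicate 3 (0.50).

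**Figure D1:**
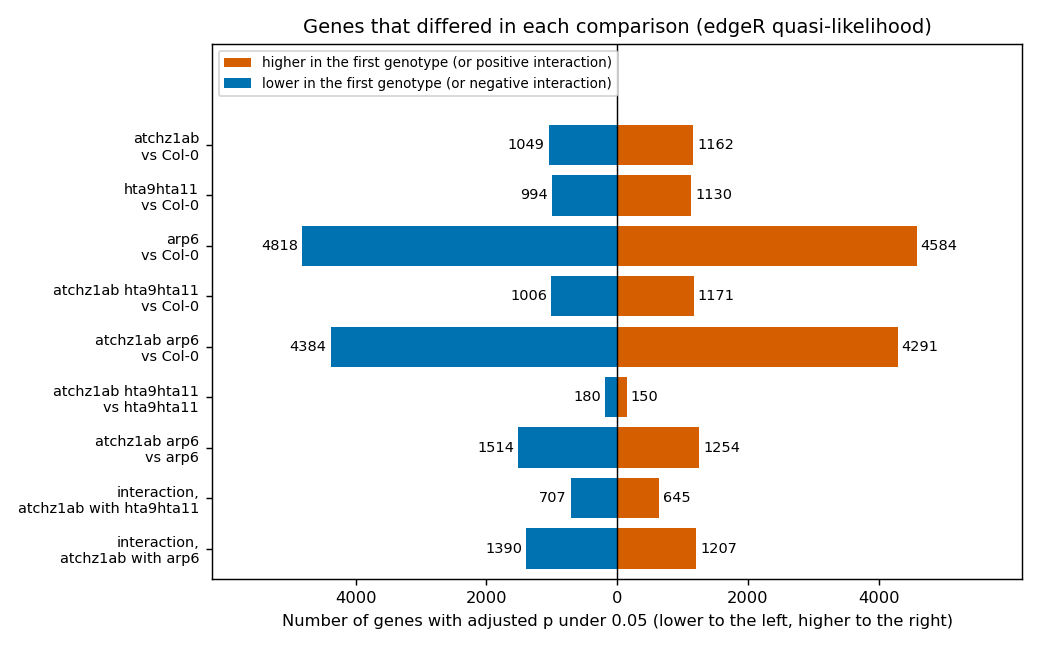
The bars give the number of genes with an edgeR adjusted p under 0.05 in each of the 7 comparisons and 2 interactions, lower in the first genotype to the left and higher to the right. The arp6 lines changed 9402 and 8675 genes against Col-0, and the addition of atchz1ab to hta9hta11 changed 330.

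Seedlings mutated in AtChz1 were compared with Col-0 to ask what the chaperones contribute to transcript levels. The DNA damage response rose in atchz1ab. SMR7 (AT3G27630), an inhibitor of cyclin-dependent kinases, went from 0.361 ± 0.339 to 7.62 ± 1.48 CPM (log2 fold change 4.38 ± 0.37, edgeR adjusted p = 7.08e-20). TSO2 (AT3G27060), a subunit of ribonucleotide reductase, rose by 1.36 ± 0.05 (156 ± 0.999 against 60.5 ± 2.24 CPM, edgeR adjusted p = 2.58e-52). At the same time genes of phosphate starvation, salicylic acid and the response to drought and cold fell. PEPC1 (AT1G17710), a phosphatase induced by phosphate starvation, changed by -3.95 ± 0.38 and PR1 (AT2G14610), a defence marker of salicylic acid, by -3.69 ± 0.37 (edgeR adjusted p = 2.01e-16 and 2.07e-15). The largest fall was that of AT1G44770 (chromosome 1, 16907537 to 16909572), which had 947 counts over the Col-0 libraries and 0 in atchz1ab, at least 334-fold lower. Whether it lies at or beside a mutated AtChz1 gene is not given in the sources used here, so that its loss is not taken as a response.

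In the DNA damage list 8 of 18 measured members rose and 1 fell (10 and 1 adjusted over the list alone), with a median log2 fold change of 0.33 (camera adjusted p = 1.81e-24). GMI1 (AT5G24280) and PARP2 (AT4G02390), both of DNA strand break repair, stood at 42.2 ± 3.69 against 9.27 ± 1.05 and 27.1 ± 2.69 against 8.4 ± 1.25 CPM. XRI1 (AT5G48720), induced by X-rays, and BRCA1 (AT4G21070) rose by 1.57 ± 0.12 and 1.60 ± 0.14. GEX1 (AT5G55490), known from gametes, had 54 against 1 counts, a ratio of 51 (8.77 to 2049.8). Of 21 phosphate starvation genes 2 rose and 10 fell (2 and 12 adjusted over the list alone; median -0.90, camera adjusted p = 3.6e-13). Among these, the non-coding RNA IPS1 (AT3G09922) stood at 0.22 ± 0.108 against 3.36 ± 0.514 CPM and the galactolipid synthase MGD3 (AT2G11810) at 1.66 ± 0.161 against 9.18 ± 0.51. The phosphate transporter PHT1;4 (AT2G38940) stood at 3.4 ± 0.485 against 11.5 ± 2.01 CPM, and the acid phosphatase PAP14 (AT2G46880) had 1 against 79 counts, a ratio of 83.7 (14.6 to 3347). The salicylic acid list held 1 risen and 10 fallen genes of 24 (1 and 12 adjusted over the list alone; median -0.56, camera adjusted p = 3.93e-08). The glucanase gene PR2 (AT3G57260) (2.55 ± 0.728 against 14.8 ± 2.9 CPM) and AIG1 (AT1G33960) (0.295 ± 0.0664 against 3.94 ± 1.63) were among the fallen. In the list for abscisic acid, drought and cold 18 of 25 fell and 0 rose (0 and 19 adjusted over the list alone; median -0.42, camera adjusted p = 9.09e-36). RAB18 (AT5G66400) and RD29A (AT5G52310), both induced by abscisic acid, fell to 103 ± 3.88 and 129.8 ± 2.42 from 179.9 ± 3.13 and 215 ± 5.92 CPM, and P5CS1 (AT2G39800), of proline synthesis, changed by -0.53 ± 0.03.

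Jasmonate and heat genes fell as lists in atchz1ab. For jasmonate and wounding 5 of 22 fell (1 and 7 adjusted over the list alone; median -0.17, or -0.13 with genes at 0 set to their bound, camera adjusted p = 0.000924). The defensin gene PDF1.2A (AT5G44420) (5.68 ± 0.322 against 15.3 ± 1.98 CPM) and the lipoxygenase gene LOX2 (AT3G45140) (575 ± 9.55 against 697 ± 10.3) were among these. For heat shock 6 of 21 fell (1 and 6 adjusted over the list alone; median -0.13, camera adjusted p = 0.0108). The small heat shock protein gene HSP17.6C (AT1G53540) stood at 0.147 ± 0.0619 against 3.03 ± 0.276 CPM. Photosynthesis genes went both ways, 8 up and 14 down of 27 (9 and 14 adjusted over the list alone; median -0.04, camera adjusted p = 4.02e-12, adjusted p = 0.0576 with an estimated correlation). RBCS2B (AT5G38420), a small subunit of Rubisco, stood at 3112 ± 38.4 against 2348 ± 10.8 CPM. The glucosinolate list was called downward with 2 risen and 6 fallen members (3 and 6 adjusted over the list alone; median -0.03, camera adjusted p = 0.0467). It lost its call with an estimated correlation (adjusted p = 0.0576), with RLE size factors (0.0513) and without Col-0 replicate 1 (0.0671) or 2 (0.0740) or atchz1ab replicate 1 (0.0554), 2 (0.0636) or 3 (0.0568). Its member TGG1 (AT5G26000), a myrosinase, stood at 2544 ± 23.5 against 2893 ± 16.3 CPM. The flowering gene FUL (AT5G60910) rose from 2.84 ± 0.682 to 7.5 ± 1.69 CPM (log2 fold change 1.41, edgeR adjusted p = 3.69e-08). MAF5 (AT5G65080), a repressor related to FLC (AT5G10140), fell from 6.05 ± 0.0961 to 3.13 ± 0.627 (-0.95, edgeR adjusted p = 0.00335). Neither flowering list was called (camera adjusted p = 0.426 and 0.372, medians 0.04 and -0.17).

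Markers of seed maturation were also higher in atchz1ab, 3 of 11 measured members with 0 lower (3 and 0 adjusted over the list alone; median 0.46, or 0.00 with genes at 0 set to their bound, camera adjusted p = 0.00618). The storage protein genes CRU3 (AT4G28520) and CRA1 (AT5G44120) stood at 5.64 ± 0.538 against 0.81 ± 0.434 and 20.2 ± 0.771 against 11.2 ± 1.63 CPM. They rose in the same libraries in which the stress genes were lower. The share of counts on organelle genes was 1.60% ± 0.00729 in atchz1ab and 2.13% ± 0.0108 in Col-0 (exact permutation p = 0.1, 2-sided, n = 3, the smallest that 3 against 3 allow). The senescence markers SAG13 (AT2G29350) (3.65 ± 1.59 against 17.3 ± 1.68 CPM) and SEN1 (AT4G35770) (92.7 ± 2.99 against 54.2 ± 6.89) moved apart, and their list was not called (camera adjusted p = 0.0876, median -0.20). In all, 2211 genes differed, 1162 higher and 1049 lower, or 11.7% of those tested. Of these, 283 changed at least 2-fold (83 higher, 200 lower), and 637 were called (218 higher, 419 lower) in the added test that assumes a coefficient of variation of 0.1.

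**Figure D2:**
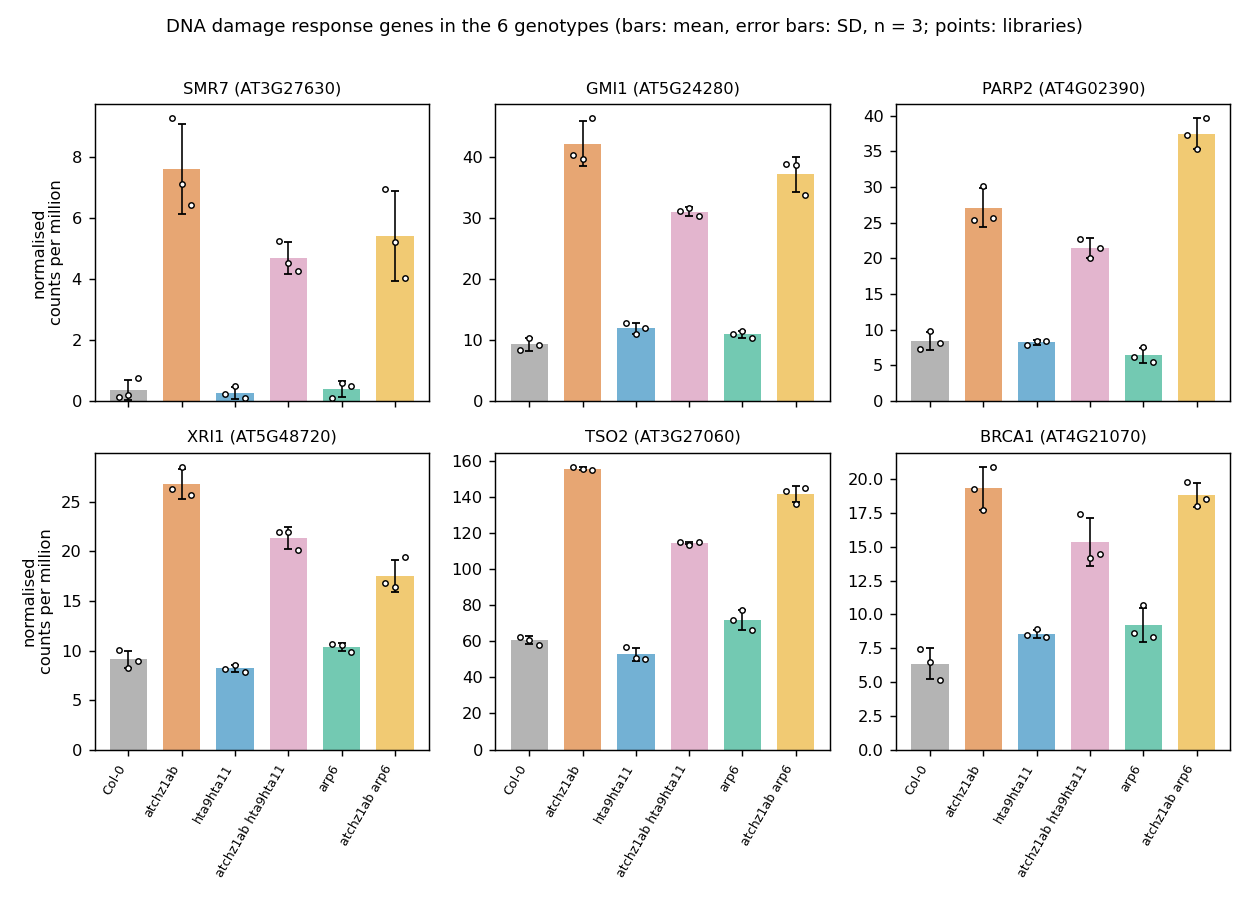
Levels (CPM) of 6 DNA damage genes in the 6 genotypes, with bars for the mean, error bars for the SD (n = 3) and points for libraries. In the 3 lines with the atchz1ab mutations TSO2 stood at 156 ± 0.999, 114 ± 0.818 and 142 ± 4.66, and in the 3 lines without them at 60.5 ± 2.24, 52.7 ± 3.66 and 71.8 ± 5.36.

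The hta9hta11 line was compared with Col-0 to ask which transcripts depend on the main H2A.Z genes. Jasmonate genes fell in it. LOX2, the lipoxygenase of jasmonate synthesis, dropped from 697 ± 10.3 to 385 ± 7.48 CPM (log2 fold change -0.86 ± 0.02, edgeR adjusted p = 3.66e-63). AOC2 (AT3G25770) and AOS (AT5G42650), of the same pathway, fell from 288 ± 10.1 and 153 ± 1.96 to 188 ± 3.21 and 98.6 ± 5.46. Defence and drought genes fell too, with PR1 at 0.677 ± 0.49 against 6.4 ± 1.24 CPM and RD29A at 139.6 ± 2.77 against 215 ± 5.92. Seed storage genes rose, CRA1 to 40.7 ± 2.61 and CRU3 to 7.48 ± 0.475 CPM. So did the floral organ gene SEP3 (AT1G24260) (5.11 ± 0.568 against 2.25 ± 0.873, log2 fold change 1.14 ± 0.22, edgeR adjusted p = 4.29e-05).

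Of 22 jasmonate and wounding genes 15 fell and 1 rose (1 and 16 adjusted over the list alone; median -0.49, camera adjusted p = 8.93e-38). The storage protein gene VSP2 (AT5G24770) stood at 126 ± 4.34 against 173 ± 4.36 CPM. Among 25 genes of abscisic acid, drought and cold 18 fell and 0 rose (0 and 18 adjusted over the list alone; median -0.34, camera adjusted p = 8.99e-29). KIN2 (AT5G15970) stood at 291 ± 0.279 against 390.4 ± 10.5 and COR15A (AT2G42540) at 107 ± 2.05 against 152 ± 2.43 CPM. The glucosinolate list had 12 fallen and 0 risen members of 26 (1 and 16 adjusted over the list alone; median -0.17, camera adjusted p = 2.42e-13). The myrosinase gene TGG2 (AT5G25980) stood at 551 ± 19.2 against 870.4 ± 2.58 CPM. In the salicylic acid list 9 of 24 fell (0 and 13 adjusted over the list alone; median -0.54, camera adjusted p = 3.06e-09). Among these were PR2 (4.58 ± 0.869 against 14.8 ± 2.9 CPM) and DMR6 (AT5G24530), which turns over salicylic acid (-1.08 ± 0.16). Phosphate starvation genes were 7 lower and 1 higher (1 and 9 adjusted over the list alone; median -0.17, camera adjusted p = 0.00299). MGD3 stood at 4.74 ± 0.38 against 9.18 ± 0.51 and the ribonuclease gene RNS1 (AT2G02990) at 3.42 ± 0.204 against 7.13 ± 1.33 CPM. For heat shock 6 fell and 0 rose (3 and 7 adjusted over the list alone; median -0.11, camera adjusted p = 0.019), a call lost without hta9hta11 replicate 3 (0.0599).

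Upward calls were made for the clock, flowering, floral and seed lists. Clock genes counted 10 risen and 0 fallen of 25 (11 and 1 adjusted over the list alone; median 0.06, camera adjusted p = 0.000639). GI (AT1G22770) stood at 191 ± 9.55 against 149 ± 7.81 and PRR7 (AT5G02810) at 179.9 ± 0.152 against 155 ± 2.26 CPM. Flowering time regulators counted 5 risen and 2 fallen of 19 (5 and 2 adjusted over the list alone; median 0.17, camera adjusted p = 0.00993), with FUL at 6.42 ± 0.722 against 2.84 ± 0.682 CPM. FLC and its relatives were not called as a list (camera adjusted p = 0.391, median -0.08). The floral list had 2 of 5 measured members up (4 and 0 adjusted over the list alone; median 1.14, camera adjusted p = 0.0081). Seed maturation had 4 of 11 up and 0 down (5 and 0 adjusted over the list alone; median 1.19, or 0.85 with genes at 0 set to their bound, camera adjusted p = 9.31e-09). The machinery list was called downward with 2 risen and 3 fallen of 17 (2 and 4 adjusted over the list alone; median -0.02, camera adjusted p = 0.000492). Its fallen members include the mutated HTA9 and HTA11, while PIE1 (AT3G12810), the ATPase of SWR1, rose by 0.25 ± 0.06 (edgeR adjusted p = 0.00055). Photosynthesis genes again went both ways, 9 up and 11 down (11 and 12 adjusted over the list alone; median 0.01, mean -0.03, camera direction down, adjusted p = 0.00313, adjusted p = 0.388 with an estimated correlation). DNA damage genes were not called as a list (camera adjusted p = 0.318, median -0.09, 0 up and 2 down), and the organelle share was 2.1% ± 0.021 (exact permutation p = 0.2, 2-sided, n = 3). In all, 2124 genes differed, 1130 higher and 994 lower (11.2% of those tested). Of these, 287 changed at least 2-fold (146 higher, 141 lower), and 640 were called (283 higher, 357 lower) with an assumed coefficient of variation of 0.1.

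The arp6 line was compared with Col-0 to ask what changes with loss of the ARP6 transcript, and it showed the widest changes. Photosynthesis genes rose, RCA (AT2G39730), which activates Rubisco, from 3579 ± 34.5 to 6557 ± 6.74 CPM and LHCA4 (AT3G47470), an antenna protein of photosystem I, from 3033 ± 25.6 to 5303 ± 10.3. Floral genes rose with them, SEP3 to 26.6 ± 1.34 CPM (log2 fold change 3.52 ± 0.17, edgeR adjusted p = 3.59e-41). The flowering repressors FLC, FLM (AT1G77080) and MAF5 fell to 1.19 ± 0.416, 26.8 ± 1.93 and 0.992 ± 0.569 CPM (edgeR adjusted p = 0.000151, 3.32e-07 and 8.92e-12, log2 fold changes -1.54, -0.50 and -2.51). FLC overlaps an opposite gene over 804 of its 1180 bases, so that its values are uncertain. Transcripts of the myrosinase TGG2 dropped to 195 ± 4.03 CPM from 870.4 ± 2.58 (-2.16 ± 0.03, edgeR adjusted p = 6.9e-107), and those of jasmonate and phosphate starvation genes fell as well.

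Of their relatives MAF2 (AT5G65050) rose (39.9 ± 0.612 against 30.5 ± 1.49 CPM) and MAF4 (AT5G65070) had 0 against 44 counts, at least 14.1-fold lower. The list was not called (1 up and 4 down of 6, 1 and 5 adjusted over the list alone, median -1.02, camera adjusted p = 0.209). Flowering activators stood higher, SOC1 (AT2G45660) at 127 ± 6 against 83.4 ± 0.918 CPM and GI at 235 ± 6.23 against 149 ± 7.81, and the repressor TEM2 (AT1G68840) lower at 3.31 ± 0.251 against 14.1 ± 1.26. Their list was not called (12 up and 6 down of 19, median 0.61, camera adjusted p = 0.226). In the floral list 4 of 5 measured members rose (4 and 0 adjusted over the list alone; median 2.37, camera adjusted p = 0.0101), among them AP1 (AT1G69120) (1.8 ± 0.266 CPM, 2.86 ± 0.57). Photosynthesis genes rose in 26 of 27 cases and fell in 1 (26 and 1 adjusted over the list alone; median 0.45, camera adjusted p = 4.2e-72). The clock list was called upward with 10 risen and 5 fallen of 25 (10 and 6 adjusted over the list alone; median 0.24, camera adjusted p = 0.0183). PRR7 stood at 292 ± 2.12 against 155 ± 2.26 CPM and LNK2 (AT3G54500) at 103 ± 5.05 against 41.7 ± 0.617. Of the machinery genes PIE1 rose to 90.8 ± 4.17 CPM and SEF (AT5G37055), another SWR1 subunit, fell from 5.86 ± 0.177 to 1.62 ± 0.781. SEF lies near a gene switched off in arp6, a limit given below. The list was not called (camera adjusted p = 0.175, 3 up and 6 down).

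Among 22 jasmonate and wounding genes 13 fell and 3 rose (3 and 13 adjusted over the list alone; median -0.66, camera adjusted p = 2.64e-06). AOC2 and VSP2 fell to 93.2 ± 1.12 and 74.6 ± 3.62 CPM, while VSP1 (AT5G24780) rose to 96.9 ± 2.77 from 39.1 ± 2.88. In the heat shock list 15 of 21 fell (0 and 15 adjusted over the list alone; median -0.79, camera adjusted p = 0.0106). The chaperone gene HSP101 (AT1G74310) stood at 8.78 ± 1.16 against 18.9 ± 0.91 CPM and DREB2A (AT5G05410), a transcription factor of drought and heat, at 10.9 ± 1.77 against 24 ± 1.13. Phosphate starvation had 16 fallen and 2 risen of 21 (2 and 16 adjusted over the list alone; median -0.83, camera adjusted p = 0.000384). RNS1 fell to 0.372 ± 0.0657 CPM and PHO2 (AT2G33770), a brake on phosphate uptake, rose to 175 ± 6.3. The glucosinolate list had 14 fallen and 4 risen (5 and 14 adjusted over the list alone; median -0.24, camera adjusted p = 1.15e-05). The list for abscisic acid, drought and cold had 17 fallen and 1 risen (1 and 18 adjusted over the list alone; median -0.56, camera adjusted p = 4.57e-07). The dehydrin genes ERD10 (AT1G20450) and COR47 (AT1G20440) stood at 60.8 ± 2.09 against 134 ± 2.74 and 202 ± 8.69 against 322 ± 9.07 CPM. Senescence markers fell in 6 of 8 cases and rose in 1 (1 and 6 adjusted over the list alone; median -0.63, camera adjusted p = 0.000644). SAG13 fell to 0.325 ± 0.377 and WRKY6 (AT1G62300) to 6.41 ± 0.712 CPM. Salicylic acid genes went both ways (5 up, 9 down, median 0.04, camera adjusted p = 0.21). PR2 fell to 1.96 ± 0.286 CPM and WRKY40 (AT1G80840) stood at 1.01 ± 0.447 against 11.3 ± 1.06. Auxin genes counted 9 up and 1 down of 22 without a call for the list (camera adjusted p = 0.21, median 0.36). SAUR20 (AT5G18020), of growth by cell expansion, stood at 11 ± 1.09 against 5.1 ± 0.829 CPM. The seed markers CRU3 (2.61 ± 0.30) and CRA1 (-0.99 ± 0.15) moved apart and their list was not called (camera adjusted p = 0.563, median 0.05). The organelle share was 2.17% ± 0.0424 (exact permutation p = 0.3, 2-sided, n = 3).

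The largest differences in arp6 were on and off states. AT2G05914, uncertain for an opposite gene, had 5374 against 2 counts, a ratio of 2791 (772 to 23054), and AT3G62475 was at least 219-fold higher. AT5G66052 had 0 against 2006 counts, at least 644-fold lower. AT3G61010 was at least 463-fold lower and ELI3-2 (AT4G37990), a gene of pathogen response, at least 303-fold. With thresholds set after seeing the data, 59 genes above 5 CPM in Col-0 (here without TMM) were under 0.3 CPM in arp6, and 20 genes showed the opposite change. In all, 9402 genes differed, 4584 higher and 4818 lower (49.7% of those tested), of which 2110 changed at least 2-fold (833 higher, 1277 lower). When genes within 250 kb of the 79 on and off genes were left out, as was chosen after seeing them, 6796 calls were left. SEP3, GI, SEF, ERD10, COR47, CYP79F1 and PARP2 lie within 250 kb of genes silent in arp6 and read again in atchz1ab arp6. Their changes in lines with arp6 cannot be told apart from differences carried in those regions, weighed below. SAG13, MGD3, PHT1;4, RAB18, TSO2, SMR7, SHM1 (AT4G37930) and GLDP2 (AT2G26080) lie within 250 kb of genes silent in arp6 that stayed under 2.5 CPM in atchz1ab arp6. Differences carried in such regions remain open as a source of their changes in lines with arp6 too.

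**Figure D3:**
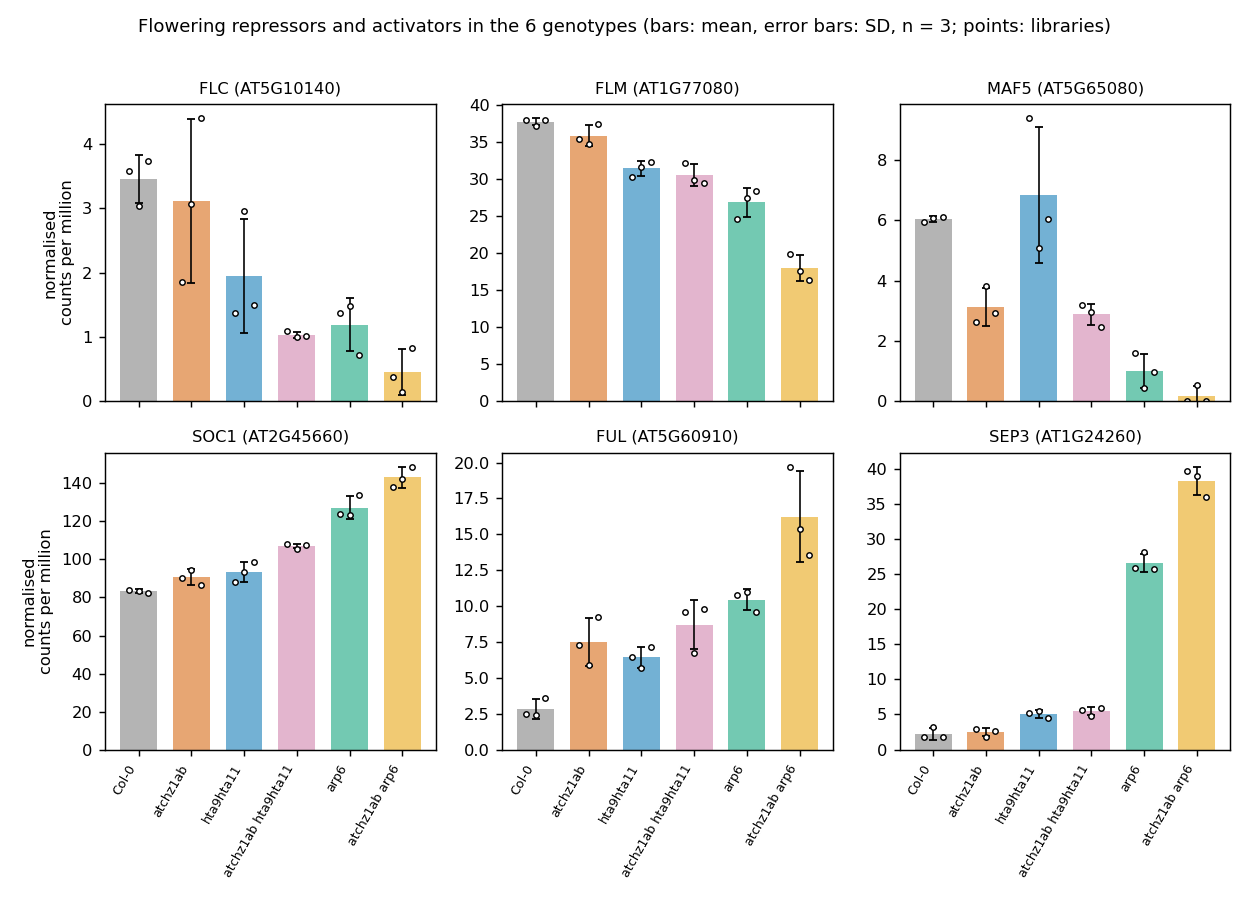
Levels (CPM) of 3 flowering repressors (FLC, FLM and MAF5) and 3 promoting or floral genes (SOC1, FUL and SEP3) in the 6 genotypes, with bars for the mean, error bars for the SD (n = 3) and points for libraries. FLM stood at 37.7 ± 0.494 in Col-0 and at 17.9 ± 1.77 in atchz1ab arp6, and SEP3 at 2.25 ± 0.873 and 38.3 ± 1.99.

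Both double lines were also set against Col-0. In atchz1ab hta9hta11 seed storage genes rose, CRA1 from 11.2 ± 1.63 to 52.7 ± 3.01 CPM and CRU3 from 0.81 ± 0.434 to 23.3 ± 1.47 (log2 fold changes 2.24 ± 0.10 and 4.87 ± 0.22, edgeR adjusted p = 7.79e-43 and 1.22e-41). The albumin genes SESA1 (AT4G27140) and SESA2 (AT4G27150) had 137 against 0 and 153 against 0 counts, at least 40.3-fold and 45-fold higher. DNA damage genes rose, TSO2 to 114 ± 0.818, GMI1 to 31.1 ± 0.695, PARP2 to 21.4 ± 1.37 and XRI1 to 21.4 ± 1.08 CPM. The repressors FLC, FLM and MAF5 fell to 1.03 ± 0.0515, 30.5 ± 1.49 and 2.87 ± 0.361 CPM (edgeR adjusted p = 0.000108, 0.00508 and 0.000846, log2 fold changes -1.72, -0.30 and -1.06). SOC1 and FUL rose to 107 ± 1.17 and 8.7 ± 1.72 CPM. Jasmonate, glucosinolate, drought and phosphate genes were lower, LOX2 at 395 ± 3.1, TGG2 at 580.0 ± 7.75, RAB18 at 105 ± 5.81 and MGD3 at 1.66 ± 0.616 CPM.

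As lists, seed maturation had 9 of 11 up (10 and 0 adjusted over the list alone; median 4.87, or 4.3 with genes at 0 set to their bound, camera adjusted p = 3.29e-44). DNA damage had 8 of 18 up (10 and 1 adjusted over the list alone; median 0.42, camera adjusted p = 1.32e-14). FLC and its relatives had 3 of 6 down (0 and 4 adjusted over the list alone; median -0.31, camera adjusted p = 0.00376). Jasmonate and wounding genes were called downward (2 up and 12 down, 2 and 15 adjusted over the list alone; median -0.38, camera adjusted p = 2.55e-26). So were glucosinolate genes (0 up and 14 down, 0 and 16 adjusted over the list alone; median -0.19, camera adjusted p = 2.15e-18). The list for abscisic acid, drought and cold was lower (0 up and 16 down, 0 and 17 adjusted over the list alone; median -0.35, camera adjusted p = 1.81e-39). Phosphate starvation was lower as well (1 up and 8 down, 1 and 8 adjusted over the list alone; median -0.31, camera adjusted p = 4.46e-09). Salicylic acid genes went the same way (1 up and 8 down, 1 and 11 adjusted over the list alone; median -0.48, camera adjusted p = 6.67e-08). The machinery list, which holds the mutated HTA9 and HTA11, was called downward (0 up and 4 down, 1 and 4 adjusted over the list alone; median -0.08, camera adjusted p = 3.28e-05). Photosynthesis genes were 8 up and 14 down (10 and 15 adjusted over the list alone; median -0.06, camera adjusted p = 8.86e-06, adjusted p = 0.176 with an estimated correlation). The organelle share was 1.73% ± 0.0049 (exact permutation p = 0.1 against Col-0, 2-sided, n = 3). In all, 2177 genes differed, 1171 higher and 1006 lower, of which 357 changed at least 2-fold (185 higher, 172 lower), and 766 were called (351 higher, 415 lower) with an assumed coefficient of variation of 0.1.

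In atchz1ab arp6 the repressors stood lowest of all genotypes, FLC at 0.449 ± 0.354, FLM at 17.9 ± 1.77 and MAF5 at 0.179 ± 0.309 CPM (edgeR adjusted p = 2.05e-08, 1.51e-19 and 6.03e-18 against Col-0, log2 fold changes -2.92, -1.07 and -4.98). FUL and SEP3 rose to 16.2 ± 3.15 and 38.3 ± 1.99 CPM. DNA damage genes rose together with photosynthesis genes, PARP2 to 37.4 ± 2.17, TSO2 to 142 ± 4.66 and LHCA4 to 4823 ± 76.7 CPM. PDF1.2A fell to 0.488 ± 0.158, MGD3 to 0.356 ± 0.211 and TGG2 to 317 ± 2.4 CPM. ADF8 (AT4G00680), an actin-binding protein gene of the root list, rose from 0.542 ± 0.262 to 11.9 ± 0.507 CPM (4.41 ± 0.31). SWEET15 (AT5G13170), a sugar transporter gene of the senescence list, rose to 7.74 ± 0.438 from 2.62 ± 0.117, and ABCA9 (AT5G61730) had 308 against 0 counts, at least 116-fold higher.

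As a list, photosynthesis was called upward (22 up and 2 down, 23 and 2 adjusted over the list alone; median 0.40, camera adjusted p = 7.88e-63). DNA damage was called upward as well (11 up and 4 down, 11 and 5 adjusted over the list alone; median 0.54, camera adjusted p = 0.000265). So was floral organ identity (4 up and 0 down, 4 and 0 adjusted over the list alone; median 2.27, camera adjusted p = 0.000684). The clock list was called too (10 and 4, 11 and 4 adjusted over the list alone; median 0.14, camera adjusted p = 0.0493), but not with an estimated correlation (adjusted p = 0.055), without Col-0 replicate 2 (0.0533) or without atchz1ab arp6 replicate 3 (0.0527). FLC and its relatives were called downward (0 up and 4 down, 0 and 4 adjusted over the list alone; median -1.99, camera adjusted p = 0.0125). Phosphate starvation genes were lower as a list (2 up and 18 down, 2 and 18 adjusted over the list alone; median -0.70, camera adjusted p = 0.000129). So were those of abscisic acid, drought and cold (2 up and 19 down, 2 and 19 adjusted over the list alone; median -0.54, camera adjusted p = 6.12e-06). Jasmonate and wounding genes followed (3 up and 14 down, 3 and 16 adjusted over the list alone; median -0.43, camera adjusted p = 0.000392). Heat shock genes were lower too (0 up and 12 down, 0 and 12 adjusted over the list alone; median -0.82, camera adjusted p = 0.0125). Senescence markers were called downward (1 up and 5 down, 1 and 5 adjusted over the list alone; median -0.69, camera adjusted p = 0.00498). Glucosinolate genes were not called as a list (11 up and 5 down, 11 and 5 adjusted over the list alone; median 0.09, camera adjusted p = 0.165). The organelle share was 1.75% ± 0.0222 (exact permutation p = 0.1 against Col-0, 2-sided, n = 3). In all, 8675 genes differed, 4291 higher and 4384 lower, of which 1793 changed at least 2-fold (762 higher, 1031 lower). With an assumed coefficient of variation of 0.1 the calls were 5566 (2574 higher, 2992 lower).

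The double line atchz1ab hta9hta11 was set against hta9hta11 to ask what the atchz1ab mutations add where HTA9 and HTA11 transcripts are already reduced. DNA damage genes rose again, TSO2 from 52.7 ± 3.66 to 114 ± 0.818 CPM (log2 fold change 1.12 ± 0.05, edgeR adjusted p = 4.5e-41). GMI1 rose by 1.38 ± 0.10, XRI1 by 1.39 ± 0.12, PARP2 by 1.39 ± 0.12 and SMR7 from 0.271 ± 0.201 to 4.68 ± 0.516 CPM. Seed storage genes rose beyond their level in hta9hta11, CRU3 from 7.48 ± 0.475 to 23.3 ± 1.47 CPM (1.63 ± 0.14, edgeR adjusted p = 7.51e-19). SESA1 had 137 against 1 counts, a ratio of 127 (22.5 to 5062), and SESA3 (AT4G27160) was at least 35.3-fold higher. RAB18, IPS1 and MGD3 fell to 105 ± 5.81, 0.397 ± 0.214 and 1.66 ± 0.616 CPM from 145 ± 1.99, 1.96 ± 0.494 and 4.74 ± 0.38. AT1G44770 had 0 against 1002 counts, at least 359.6-fold lower, with the limit given above.

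Of 18 DNA damage genes 10 rose and 0 fell (12 and 0 adjusted over the list alone; median 0.61, camera adjusted p = 8.68e-45). Of 11 seed genes 7 rose and 0 fell (9 and 0 adjusted over the list alone; median 1.63, camera adjusted p = 1.23e-44). In the same lines the organelle share went from 2.1% ± 0.021 to 1.73% ± 0.0049 (exact permutation p = 0.1, 2-sided, n = 3). The jasmonate list was called upward with 3 risen and 1 fallen (4 and 1 adjusted over the list alone; median 0.07, camera adjusted p = 0.0213). VSP2 stood at 148 ± 4.26 against 126 ± 4.34 CPM. Phosphate starvation genes were called downward (0 up and 6 down, 1 and 7 adjusted over the list alone; median -0.15, camera adjusted p = 8.45e-06). The list for abscisic acid, drought and cold went the same way (0 up and 3 down, 1 and 6 adjusted over the list alone; median -0.06, camera adjusted p = 0.000396). FLC with its relatives was lower too (0 up and 1 down, 0 and 1 adjusted over the list alone; median -0.46, camera adjusted p = 0.00308). The called member of this list, MAF5, stood at 2.87 ± 0.361 against 6.85 ± 2.27 CPM (-1.25 ± 0.24, edgeR adjusted p = 0.000153), and its call was lost without hta9hta11 replicate 1 (-0.95). Another 4 lists were called at adjusted p from 0.0204 to 0.0322 and lost their calls without 1 library. These were glucosinolates (0 and 3, 2 and 6 adjusted over the list alone; median -0.03) and the clock (0 and 0, 0 and 0 adjusted over the list alone; median -0.04), both at 0.0741 without hta9hta11 replicate 2 and at 0.06 without atchz1ab hta9hta11 replicate 2. The clock stood at 0.0768 without atchz1ab hta9hta11 replicate 3. Heat shock (0 and 0, 0 and 0 adjusted over the list alone; median 0.13) had an adjusted p = 0.0559 with an estimated correlation, 0.138 without hta9hta11 replicate 3 and 0.0783 without atchz1ab hta9hta11 replicate 1. Photosynthesis (1 and 5, 4 and 7 adjusted over the list alone; median -0.01) had an adjusted p = 0.537 with an estimated correlation, 0.202 without hta9hta11 replicate 3 and 0.107 without atchz1ab hta9hta11 replicate 1. Without replicate 2 of the double line heat shock stood at 0.06, and without replicate 3 photosynthesis at 0.0768. In all, 330 genes differed, 150 higher and 180 lower (1.75% of those tested), and 61 changed at least 2-fold (35 higher, 26 lower). The count was 197 with DESeq2 (92 higher, 105 lower), 119 with an assumed coefficient of variation of 0.1, and between 219 without atchz1ab hta9hta11 replicate 1 and 249 when single libraries were left out.

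The double line atchz1ab arp6 was set against arp6 to ask the same where ARP6 is lost. DNA damage genes rose here as well, PARP2 from 6.38 ± 1.07 to 37.4 ± 2.17 CPM and TSO2 from 71.8 ± 5.36 to 142 ± 4.66 (log2 fold changes 2.57 ± 0.12 and 0.98 ± 0.05, edgeR adjusted p = 1.82e-39 and 6.92e-38). SMR7 rose to 5.4 ± 1.47 and GMI1 to 37.2 ± 2.9 CPM. Of the genes that had fallen in arp6, VSP2 rose from 74.6 ± 3.62 to 154 ± 1.98 CPM (1.04 ± 0.04, edgeR adjusted p = 4.98e-44), TGG2 from 195 ± 4.03 to 317 ± 2.4. PR1 and PR2 rose to 3.5 ± 0.492 and 5.81 ± 1.22 from 1.03 ± 0.202 and 1.96 ± 0.286. RCA fell from 6557 ± 6.74 to 5231 ± 121 CPM and FLM from 26.8 ± 1.93 to 17.9 ± 1.77 (-0.57 ± 0.10, edgeR adjusted p = 2e-06), while SEP3 rose by 0.53 ± 0.10.

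Of 18 DNA damage genes 10 rose and 0 fell (11 and 0 adjusted over the list alone; median 0.66, camera adjusted p = 2.41e-17). Glucosinolate genes rose in 15 of 26 cases (17 and 1 adjusted over the list alone; median 0.24, camera adjusted p = 1.25e-13). CYP79F1 (AT1G16410), of aliphatic glucosinolate synthesis, stood at 283 ± 9.31 against 210.3 ± 3.75 CPM. The jasmonate list was called upward with 8 up and 4 down (9 and 5 adjusted over the list alone; median 0.11, camera adjusted p = 0.000491). Photosynthesis was called downward with 1 up and 18 down (1 and 19 adjusted over the list alone; median -0.09, camera adjusted p = 2.39e-17). The list for abscisic acid, drought and cold was called upward (7 up and 2 down, 8 and 3 adjusted over the list alone; median 0.06, camera adjusted p = 0.0248, or adjusted p = 0.0571 with an estimated correlation). Root markers were called upward (1 up and 0 down, 1 and 0 adjusted over the list alone; median 0.01, camera adjusted p = 0.0273, or adjusted p = 0.0602 with an estimated correlation). Senescence markers were higher as a list (3 up and 0 down, 3 and 0 adjusted over the list alone; median 0.17, camera adjusted p = 0.0273, or adjusted p = 0.0602 with an estimated correlation). The root list rested on ADF8 at 11.9 ± 0.507 against 0.692 ± 0.348 CPM, and its adjusted p was 0.0709 without arp6 replicate 2. Salicylic acid genes were not called as a list (3 up and 1 down, 3 and 1 adjusted over the list alone; median 0.18, camera adjusted p = 0.124). Phosphate starvation was not called (2 up and 1 down, 2 and 1 adjusted over the list alone; median 0.11, camera adjusted p = 0.655), nor was heat shock (4 up and 1 down, 4 and 1 adjusted over the list alone; median 0.07, camera adjusted p = 0.36). Seed maturation was not called (camera adjusted p = 0.0582, median -0.97), though CRA1 and OLEO1 (AT4G25140) changed by -1.10 and -1.79. The organelle share went from 2.17% ± 0.0424 to 1.75% ± 0.0222 (exact permutation p = 0.1, 2-sided, n = 3). AT5G36930, without reads in arp6, was read in the double line, with 483 against 0 counts and at least 176-fold higher. WNK9 (AT5G28080) and AT1G22120 were at least 28.1-fold and 49.8-fold lower. AT1G22120 was newly transcribed in arp6, with 0 counts in Col-0, 163 in arp6 and 0 in the double line. It lies within 250 kb of a gene silent in arp6 and read again in the double line, as AT5G36930 itself was. The values of AT1G22120 and AT5G36930 thus cannot be told apart from a difference in those regions, weighed below. In all, 2768 genes differed, 1254 higher and 1514 lower (14.6% of those tested), of which 368 changed at least 2-fold (256 higher, 112 lower) and 839 were called (510 higher, 329 lower) with an assumed coefficient of variation of 0.1. The count was 1944 with genes near the on and off genes left out.

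**Figure D4:**
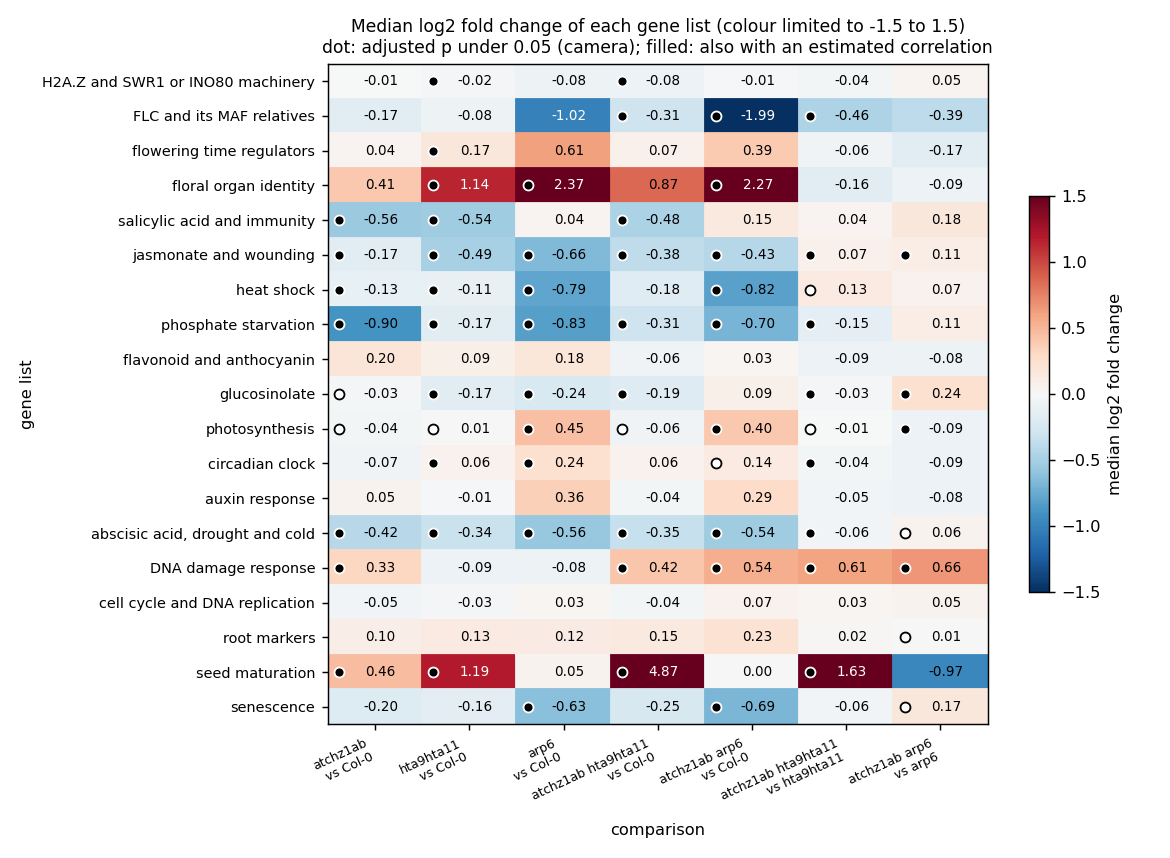
The median log2 fold change of each of the 19 gene lists (vertical) in each of the 7 comparisons (horizontal), coloured from blue (lower) to red (higher) and limited to -1.5 and 1.5, with dots for camera calls, filled where they held with an estimated correlation. DNA damage was called upward in all 5 comparisons that involve the atchz1ab mutations, with medians from 0.33 to 0.66.

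Across the 19 lists camera called 9, 12, 9, 10, 10, 10 and 7 in the 7 comparisons in the order given here, and 7, 11, 9, 9, 9, 8 and 4 held with an estimated correlation. Flavonoid and anthocyanin, auxin response and cell cycle genes were called as lists in none of the 7. Their camera adjusted p in atchz1ab was 0.143, 0.617 and 0.45 (medians 0.20, 0.05 and -0.05), although CHS (AT5G13930), the entry enzyme of flavonoid synthesis, rose there by 0.44 ± 0.08. The root list stood at 0.426 in atchz1ab and 0.157 in hta9hta11 (medians 0.10 and 0.13). By fry, whose test asks whether a list moves one way on balance, 14, 16, 17, 16, 18, 10 and 16 lists were called, and 16, 18, 18, 17, 19, 14 and 16 by its mixed p.

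The calls of the single mutants were compared for shared genes. Of the genes called in atchz1ab and in hta9hta11, 469 were higher and 427 lower in both, where independent lists would share 69.5 and 55.2, and 58 moved in opposite directions. SAG13, PR1, RD29A and LOX2 were lower in both and CRU3 and CRA1 higher. The correlation of fold changes across genes was 0.432, against a mean of 0.511 in 20 simulations of unchanged groups sharing the Col-0 libraries, in which 0.5 genes on average and at most 2 were called in the same direction. The covariance was 0.0626 against 0.0179 simulated, a difference of 0.0446. For atchz1ab and arp6 644 genes were higher and 569 lower in both (281.7 and 267.3 by independence), 453 went apart, the correlation was 0.247 (simulated 0.5) and the covariance exceeded the simulated one by 0.0819. For hta9hta11 and arp6 the numbers were 827 and 668 (274.0 and 253.3), 258, 0.390 (simulated 0.497) and 0.133. In all 3 lines 340 genes were higher and 309 lower. Genes are not independent replicates, the 3 Col-0 libraries are too few to be split, and part of each excess may come from the shared controls.

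The effect of the atchz1ab mutations was read in 3 backgrounds, against Col-0, hta9hta11 and arp6. In all 3, 150 genes were called, 38 higher and 60 lower in each. Many of the 60 are plastid or mitochondrial genes, and 18S and 5.8S ribosomal RNA genes are among them. Lower calls shared between backgrounds may thus in part reflect which RNA was carried into the libraries, as weighed below. Between the Col-0 and hta9hta11 backgrounds 139 calls went the same way (46 higher and 93 lower, with 9.22 and 9.99 by independence) and 59 the opposite way. Between the Col-0 and arp6 backgrounds 398 went the same way and 442 the opposite way, and between the hta9hta11 and arp6 backgrounds 169 and 34. The DNA damage genes SMR7, TSO2, GMI1, PARP2, XRI1 and BRCA1 were among those higher in all 3.

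**Figure D5:**
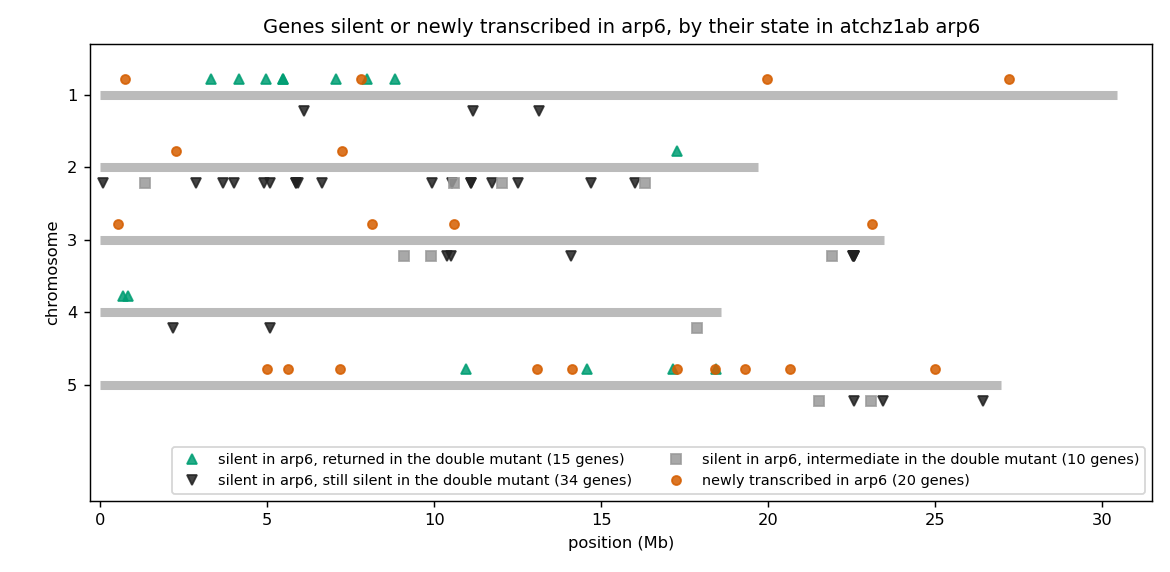
The 5 chromosomes in Mb of TAIR10.1, with symbols for 59 genes read in Col-0 and silent in arp6, split by their level in atchz1ab arp6 into returned (15, triangles above), still silent (34, triangles below) and intermediate (10, squares), and for 20 genes newly transcribed in arp6 (circles). Returned genes lie on chromosomes 1, 2, 4 and 5, and the 22 genes on chromosome 2 that did not return lie between 79779 and 16299205.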

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

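Whether the atchz1ab mutations act differently in another background was tested as an interaction, the log2 fold change between double line and parent minus that between atchz1ab and Col-0. Every value in this part, unless given as not called, was singled out because that test of the difference between the groups passed (edgeR or camera adjusted p under 0.05, n = 3 in each of 4 genotypes). Above 0 the change with the atchz1ab mutations was higher in the mutant background than in Col-0. With hta9hta11 1352 genes were called, 645 higher and 707 lower, 193 of them at least 2-fold (145 and 48), and 276 with an assumed coefficient of variation of 0.1. With arp6 2597 genes were called, 1207 higher and 1390 lower, 484 of them at least 2-fold (355 and 129), and 693 with that assumption. The 12 libraries of each interaction were also regrouped at random across all 4 genotypes, which was planned. With hta9hta11 1 of 100 splits gave 1352 or more, the real one, and the highest other gave 337. These splits put unlike genotypes into 1 group, which widens the spread within groups and can lower the calls. They therefore cannot exclude chance, or a difference between the samples, as the source of this count. With arp6 7 of 100 splits gave 2597 or more, the highest other 4948, and the other 6 put 0, 1, 5 or 6 of the arp6 libraries on the positive side, as 9 of the 100 splits do. A split that calls so many genes points to the structure of the samples, here the gap between arp6 and Col-0, and a count of this size also arises from it.

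Stress genes that fell with atchz1ab in Col-0 had higher values of this difference in hta9hta11. The fall by which they were picked is the change subtracted here, so that values above 0 are in part built in. Some had already fallen in hta9hta11 and had little room to fall further, as PR1 above and TAT3, at 0.95 CPM without TMM there against 6.067 in Col-0. PEPC1 had more, at 3.625 against 6.567. The 2 defence genes PR1 and PR2 differed by 3.67 ± 0.68 and 2.96 ± 0.29, AIG1 by 3.96 ± 0.62, the phosphate genes PEPC1, PAP14 and PHT1;4 by 2.90 ± 0.54, 4.82 ± 0.92 and 1.54 ± 0.28, and the drought genes RAB18, RD29A, P5CS1 and KIN2 by 0.35, 0.67, 0.41 and 0.37. For PAP14, at 1 count in atchz1ab, the fitted value is no bound. The heat shock genes HSP17.6C and HSP17.6II (AT5G12020), at 4 and 5 counts in atchz1ab, differed by 6.36 ± 0.95 and 5.02 ± 0.83, and the jasmonate genes LOX2, PDF1.2A and TAT3 (AT2G24850) stood at 0.32, 1.27 and 2.91 and SAG13 at 2.56. As lists, abscisic acid with drought and cold (14 higher and 0 lower, median 0.39, camera adjusted p = 1.22e-19), salicylic acid (5 and 0, 0.47, adjusted p = 1.23e-06), jasmonate (6 and 0, 0.23, 2.69e-05), phosphate starvation (7 and 2, 0.60, 0.000174) and heat shock (5 and 0, 0.17, 0.000355) were called upward. Adjusted over the list alone, the counts were 16 and 0, 9 and 0, 9 and 0, 8 and 2, and 5 and 0. The DNA damage genes TSO2, GMI1 and BRCA1 (-0.25, -0.80 and -0.74), the seed genes CRU3 and CRA1 (-1.2 and -0.48) and FUL (-0.97) stood below 0, as did CHS (-0.46) and the histone chaperone gene NRP1 (AT1G74560) (-0.23) and ESM1 (AT3G14210) (-0.41). The seed list was not called (median 0.72, camera adjusted p = 0.446), nor was the DNA damage list (median 0.01, camera adjusted p = 0.446).

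In hta9hta11 the 5 smallest adjusted p upward were those of LHCB1.1 (AT1G29920) (0.96), CRT3 (AT1G08450) (2.56), GRP3S (AT2G05380) (0.80), GLT1 (AT5G53460) (0.58) and LHCB1.3 (AT1G29930) (0.35), and downward GLDP1 (AT4G33010) (-0.60), CA1 (AT3G01500) (-0.49), RBCS2B (-0.51), CA2 (AT5G14740) (-0.36) and AT5G35935 (-3.06). RCA (-0.19), HPR (AT1G68010) (-0.35), AGT (AT2G13360) (-0.23), GOX1 (AT3G14420) (-0.32), SHM1 (AT4G37930) (-0.19) and GLDP2 (AT2G26080) (-0.29) were lower too. LHCB1.1 and LHCB1.3 have near-identical copies, and CA1 and GLT1 overlap other genes, so that these values are uncertain. The photosynthesis list had 12 higher and 10 lower members (12 and 11 adjusted over the list alone; median 0.01, camera adjusted p = 1.23e-06, adjusted p = 0.221 with an estimated correlation), and the flavonoid list 0 and 1 (0 and 3 adjusted over the list alone; median -0.37, camera adjusted p = 0.0181). Of the 245 tested genes picked by the naming rule in any comparison or looked up for the text, 84 were called here and 114 with arp6.

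In arp6 the difference was above 0 for named stress genes too, though the heat shock list was not called here. Both interactions subtract the same change between atchz1ab and Col-0, so that agreement of this kind is in part built in, and a difference in the samples of these 2 lines enters both. PR1 differed by 5.41 ± 0.53, PR2 by 4.12 ± 0.33, AIG1 by 4.41 ± 0.87, PEPC1 by 4.06 ± 1.3, PHT1;4 by 2.35 ± 0.36, HSP17.6C by 3.97 ± 0.83, TAT3 by 4.88 ± 1.2 and SAG13 by 4.48 ± 0.53. TAT3 had 1 count in arp6, so that its fitted value is no bound. PEPC1 had 4 counts in arp6 and 4 in the double line, so that it had little room to fall there, and AIG1 had 9 and 14. RAB18, RD29A, P5CS1, KIN2 and COR15B (AT2G42530) stood at 1.04, 1.09, 0.52, 0.62 and 0.23, and LOX2 and VSP2 at 0.30 and 0.95. Among glucosinolate genes TGG1, TGG2, MAM3 (AT5G23020), CYP79F1 and IGMT4 (AT1G21130) stood at 0.26, 0.72, 1.25, 0.43 and 1.93. The list for abscisic acid, drought and cold (20 higher and 0 lower, median 0.56, camera adjusted p = 2.3e-25), glucosinolates (14 and 1, 0.34, adjusted p = 1.27e-13), salicylic acid (11 and 0, 0.81, 3.1e-07), jasmonate (11 and 1, 0.32, 7.32e-07), phosphate starvation (7 and 0, 0.97, 0.00147) and senescence (2 and 0, 0.37, 0.0105) were called upward and seed maturation downward (0 and 4, -1.44, 0.00147). Adjusted over the list alone, these counts were 20 and 0, 16 and 1, 13 and 0, 12 and 2, 8 and 2, 2 and 0, and 0 and 5. The seed genes CRU3, CRA1 and OLEO1 stood at -3.47, -1.95 and -3.90, and the flowering genes FUL, AP1 and FLM at -0.76, -2.11 and -0.50. Of the DNA damage genes PARP2 rose more in arp6 than in Col-0 (0.89), as did the polymerase subunit gene POLD4 (AT1G09815) (0.79), and TSO2, XRI1 and BRCA1 rose less (-0.38, -0.80 and -0.55). The DNA damage list was not called here. PARP2, POLD4, CYP79F1 and AT1G23130 lie within 250 kb of genes silent in arp6 and read again in the double line. Their values thus cannot be told apart from a difference in those regions, weighed below. ADF8 (2.96), AT1G23130 (5.54), GRP3S (1.64), CRT3 (2.60) and LHCB1.1 (0.53) were higher, and GLDP1 (-0.70), CA1 (-0.66), AT2G10940 (-0.80), RCA (-0.45), GLDP2 (-0.67), RBCS2B (-0.41), CHS (-0.43), HPR (-0.55), AGT (-0.29), GOX1 (-0.40) and SHM1 (-0.30) lower. AT5G36930 (10.34) and AT5G28919 (11.31) had 0 counts in arp6, so that these values are no bounds. Both are among the genes silent in arp6 and read again in the double line, and carry the same limit.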

How the results depend on the processing

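Of the counts of called genes and lists under the alternatives, those not given here stayed within 1.5 times the count reported, and no named gene or list reversed. The larger side did turn in arp6 (4584 higher, 4818 lower) with RLE size factors (4720, 4714), DESeq2 (4214, 4153) and only the libraries compared (4605, 4551). It turned likewise in atchz1ab arp6 against Col-0 (4291, 4384 before; 4370, 4311, then 3894, 3748 and 4188, 4125), also without its replicates 1 and 3 (3921, 3875 and 3977, 3975), and in atchz1ab hta9hta11 against hta9hta11 (150, 180) without organelle genes (151, 139) and at 2-fold (35, 26). The 2-fold threshold, a stricter test by construction, left 283, 287, 2110, 357, 1793, 61 and 368 genes in the 7 comparisons in the order of the report, and 193 and 484 in the interactions with hta9hta11 and arp6. The assumed coefficient of variation of 0.1, added after seeing the data and wider than the estimate of 3.08%, left 637, 640, 766, 5566, 119 and 839 genes in all comparisons but that of arp6 with Col-0, 276 and 693 in the interactions, and 224, 337 and 449 shared calls of the single mutants (896, 1213 and 1495 before). It turned the larger side to lower in atchz1ab (218, 419), hta9hta11 (283, 357), atchz1ab hta9hta11 against Col-0 (351, 415) and the shared calls (53, 171; 80, 257; 178, 271), and to higher in atchz1ab arp6 against arp6 (510, 329) and the interactions (194, 82 and 478, 215). At 2-fold it turned alike in atchz1ab (83, 200), atchz1ab arp6 against arp6 (256, 112) and the interactions (145, 48 and 355, 129). For atchz1ab hta9hta11 against hta9hta11 DESeq2 called 197 instead of 330, and without 1 library the count ran from 219 to 249, fewer samples being the construction of that alternative. The cause of the DESeq2 difference was not tested. By fry, which does not compare a list with other genes, 14 lists were called in atchz1ab, 17 in arp6, 16 and 18 in the double lines against Col-0, 16 in atchz1ab arp6 against arp6 (4 with an estimated correlation), and 12 and 15 in the interactions. Without genes near the on and off genes, added after seeing the data, 6796, 6294, 1944 and 1840 calls were left in arp6, in atchz1ab arp6 against Col-0 and against arp6, and in the interaction with arp6.

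Without 1 library the other comparisons ran from 1770 to 1894 (atchz1ab), 1624 to 1722 (hta9hta11), 8506 to 8845 (arp6), 1700 to 1805 and 7769 to 8007 (double lines against Col-0) and 2255 to 2402 (atchz1ab arp6 against arp6). Among 3972 tests of named genes under these fits 3789 kept their side of the threshold, 158 lost their call and 25 gained one. DESeq2 ended 27 calls of named genes, limma-voom 9, the assumed variation 106, no filter 5, a fit of only the libraries compared 2, and RLE size factors and the replicate block 1 each. Replicate numbers did not pair the libraries, with correlations of residuals from -0.0267 to 0.0296 between genotypes and 3 of 18 libraries closest to others of their number, and as a block they gave 2196, 2102, 9388, 2161, 8644, 324 and 2728 calls. Scaling moved the share of higher genes by under 10 points, most in atchz1ab hta9hta11 against hta9hta11, from 45.45% to 52.07% without organelle genes. Small changes were often missed, with 17 of 50 simulated changes of 1.25-fold and 39 of 50 of 1.5-fold recovered.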

Other observations

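The genes of the next 2 paragraphs were chosen after their values were seen. Among the 98 genes that changed the same way with atchz1ab in all 3 backgrounds were 2 transcription factor genes known from the DNA damage response. NAC044 (AT3G01600) stood at 1.71 ± 0.26, 1.04 ± 0.27 and 2.24 ± 0.29 and NAC103 (AT5G64060) at 1.96 ± 0.34, 1.83 ± 0.29 and 2.18 ± 0.29 against Col-0, hta9hta11 and arp6. TK1a (AT3G07800), a thymidine kinase that feeds DNA synthesis, rose by 1.26 ± 0.10, 1.16 ± 0.10 and 1.09 ± 0.12, and POLD4, a small subunit of DNA polymerase delta, by 0.51 ± 0.11, 0.53 ± 0.11 and 1.3 ± 0.14. ESM1, which steers the breakdown of glucosinolates, changed by -0.50 ± 0.03, -0.91 ± 0.03 and -0.75 ± 0.13. The plastid transcripts rbcL (ATCG00490), for the large subunit of Rubisco, and psbA (ATCG00020), for a core protein of photosystem II, changed by -0.69 ± 0.01, -0.47 ± 0.01 and -0.48 ± 0.01 and by -0.68 ± 0.02, -0.47 ± 0.01 and -0.55 ± 0.02.

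Called higher in all 3 single mutants were 5 genes of photorespiration, the pathway that recycles the product of Rubisco's reaction with oxygen, of which no list was tested. In atchz1ab, hta9hta11 and arp6 against Col-0, HPR, which reduces hydroxypyruvate, stood at 0.33 ± 0.02, 0.21 ± 0.02 and 0.40 ± 0.02. The glycolate oxidase gene GOX1 stood at 0.25 ± 0.02, 0.17 ± 0.02 and 0.37 ± 0.02, and SHM1, of serine formation, at 0.19 ± 0.01, 0.15 ± 0.01 and 0.55 ± 0.01. AGT, an aminotransferase, stood at 0.22 ± 0.02, 0.20 ± 0.02 and 0.15 ± 0.02, and GLDP2, of glycine breakdown, at 0.25 ± 0.02, 0.31 ± 0.02 and 0.56 ± 0.02. CRT3, a calreticulin gene, fell in atchz1ab to 9.3 ± 2.34 from 54.6 ± 2.27 CPM (-2.55 ± 0.09) and stood at 51.9 ± 1.04 and 66 ± 2.77 in the double lines. A direct comparison of atchz1ab with hta9hta11, added after seeing the data, called 2024 genes (978 higher, 1046 lower), with DNA damage (11 of 18 members higher, camera adjusted p = 2.74e-35) and jasmonate genes (11 higher and 1 lower, adjusted p = 2.43e-18) higher in atchz1ab. Phosphate starvation was lower (0 higher and 10 lower, camera adjusted p = 1.08e-06), as was the clock (1 and 8, camera adjusted p = 0.000126). So was photosynthesis (4 and 14, camera adjusted p = 1.05e-05, or 0.218 with an estimated correlation). The abscisic acid, seed and floral lists were called lower too, and the glucosinolate and machinery lists higher. The floral call (camera adjusted p = 0.0497) was lost with an estimated correlation (adjusted p = 0.0899). The machinery list holds HTA9 and HTA11, mutated in hta9hta11, so that its call in part follows from the genotypes compared.

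The tests of the 3 patterns below were chosen once the results were known, except those of the neighbours of returned genes and of the few abundant organelle genes, chosen before.

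Of the 59 genes silent in arp6, 15 were read again in atchz1ab arp6, among them MIOX1 (AT1G14520) (6.337, 0.07957 and 6.377 CPM without TMM in Col-0, arp6 and the double line) and AGL87 (AT1G22590) (29.16, 0.2607 and 13.81). They lie in runs, on chromosome 1 from 3328971 to 5464241 and 7065494 to 8837007, on chromosome 2 from 17271143 to 17274394, on chromosome 4 from 690643 to 828824 and on chromosome 5 from 10940033 to 18432430. The 6 switches along the chromosomes between these and the other genes silent in arp6, against a mean of 20.81 in 10000 random orders and 15 to 26 in the central 95% of them (permutation p = 1e-04), fit segments of another accession that the arp6 line may carry and the double line has lost. Other genes within 250 kb of the returned genes lost over 50% of their arp6 change in 41.78% of 146 cases, against 10.34% of 203 near silent genes, a difference of 31.44 points (Fisher's exact p = 1.62e-11), which fits this too. Among genes near neither kind the share was 16.7% of 1677, so that the excess over these is smaller. Neighbours in 1 run are not independent, and this p-value may be too small. Silencing through loss of ARP6, undone by the atchz1ab mutations, cannot be told apart from this: 13 returned genes stood above 2.5 CPM in every library of the double line, but they were chosen by their level there. The 34 genes silent in both arp6 lines include ARP6, the gene mutated in them, whose silence follows from its mutation. ARP6 also stood among the 59 genes of the switch test. For the other genes silent in both lines the 2 explanations cannot be told apart either. DNA sequence of the arp6 line in these intervals would test it.

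Stress genes were lower in atchz1ab and in hta9hta11 against the same Col-0 libraries. If a difference in growth or handling of the Col-0 samples were the cause, both lines should stand alike, but the phosphate starvation list differed between them (camera adjusted p = 1.08e-06), as did that of abscisic acid, drought and cold (0.0143). That difference between the lines cannot come from the Col-0 samples, but the fall that both share in these lists still may. For the salicylic acid list (camera adjusted p = 0.863) a cause in the Col-0 samples cannot be told apart from an effect of the mutations either. The 427 genes lower in both had medians of -0.4403 and -0.4291, and 0.05018 for atchz1ab in the hta9hta11 background, which could come from a shared target as well as from the Col-0 samples. Further Col-0 samples grown beside these lines would test it.

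The share of organelle transcripts was smaller in all lines with atchz1ab. A single even drop of organelle RNA carried through poly(A) selection is excluded as the whole cause, as the log2 changes of 33 abundant organelle genes in atchz1ab had an SD of 0.3417 against a median SE of 0.03801. It is not excluded as a part. Of the 33, 19, 20 and 26 were called lower in Col-0, hta9hta11 and arp6 backgrounds and 5, 1 and 0 higher, with medians of -0.3744, -0.2953 and -0.2665. A few abundant genes are excluded as the whole cause, though not as a part of it, since without the top 5 the share was still 0.737% in atchz1ab and 0.9458% in Col-0. Less carry-over of RNA without poly(A) tails remains possible, as 18S ribosomal RNA genes were lower in all 3 backgrounds (largest edgeR adjusted p = 0.0199, log2 fold change -0.57). The gene copies are alike and the 5.8S genes moved apart, so that it cannot be told apart from a change in organelle transcripts. Libraries made by removal of ribosomal RNA would test it.

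The grouping of the 3 libraries against 3 in each comparison, planned as a test, was set against the 9 other splits of the same 6 libraries. The real split gave 2211, 2124, 9402, 2177, 8675, 330 and 2768 calls in the order of the report and the highest other 1, 2, 0, 0, 0, 4 and 1. In each comparison 1 of 10 splits, the real one, reached its count, and 10 splits are too few for more than that. The interactions stand at 1 and 7 of 100 splits.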
